A study of Homo sapiens with 2 samples.

How the data were processed

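A pair of droplet libraries of 1 pool of established lung adenocarcinoma lines (A549, HCC827, H838, H1975 and H2228) were measured by single cell RNA sequencing of polyA RNA with 10x version 3 chemistry. Per the labels, the lines were grown apart in medium with 10% serum at 37 degrees, counted, and pooled in about equal numbers. The labels describe both libraries alike, so they form 1 group with 2 replicates, Lib10 as replicate 1 and Lib90 as replicate 2. The deposited count tables hold raw UMI counts, whole numbers per gene and cell barcode, which the authors had not normalized. The submitters' notes name Cell Ranger, with no version, and build GRCh38.p10, and per the labels the barcode lies in bases 1 to 16 and the UMI in bases 17 to 26 of read 1. Read 1 has 28 bases per the run sheet and the UMI of version 3 chemistry runs to its end, so the label leaves 2 bases of it out; the UMI length behind the deposited counts is not given in the sources used here, and a shortened UMI would count fewer molecules. A deposited barcode list holds 1 count per barcode beside its sequence, in a unit that the files do not state, and only its sequences were used. The deposited run sheet puts both libraries on 1 flow cell with 4 lanes and read lengths of 28 and 91 bases, so there was no sequencing batch to set apart.

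The Lib10 table lists 32680 genes by Ensembl identifier, of which 32620 matched a symbol, and 1000 barcodes. The Lib90 table lists 38816 genes, of which 38741 matched, and 3000 barcodes. Coordinates are those of GENCODE 29 on GRCh38. A barcode was kept as a cell if its UMI total was at least 0.1 of the library's 99th percentile barcode (27923 UMIs in Lib10 and 22039 in Lib90), its mitochondrial share was under 25% and Scrublet did not call it a doublet. In Lib10, 182 barcodes reached the minimum, 12 were removed for mitochondrial share and 1 as a doublet, leaving 169 cells with a median of 168248 UMIs (quartiles 132082 to 220164) and 11371 genes. In Lib90, 1403 reached it, 57 and 14 were removed, and 1332 cells were left with a median of 107742 UMIs (87243 to 135483) and 10022 genes.

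The 1501 cells were clustered together with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9): counts scaled per cell and log transformed, 2000 variable genes, 20 principal components, 15 neighbors, Leiden resolution 0.3. The 7 clusters each held over 3% of the cells, the minimum set. Each cluster was named after the cell line whose marker list had the most raised members, provided that at least 3 and most of the detected members were raised, a member being raised at 5 CPM and 2 times the median of the clusters. The marker lists were fixed before the data were examined; the naming thresholds were set after, when 3 raised members alone would have named a cluster H2228-like for 3 of its 7 markers. Both A549-like clusters, of 284 and 96 cells, were joined, which gave 6 classes. Among the 10 genes with the largest fold of each of these clusters, 3 and 3 were A549 markers and 3 and 4 were H838 markers, an overlap foreseen when the lists were fixed, since both lines carry KEAP1 mutations. In HCC827-like cells the top 10 held 1 HCC827 marker and 1 H2228 marker (LCN2), and in H2228-like cells 3 H2228 markers and 0 of another list.

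Counts were summed per library and class into 12 sums. So that no gene helped to define the classes it was tested between, each gene was summed over clusters made from the random 50% of the genes (seed 1) that did not hold it; the clusterings from the 2 sets of genes put 1495 of 1501 cells (99.6%) in the same class. After filterByExpr, 19354 genes were tested with edgeR 4.0.16 (R 4.3.3; TMM factors, glmQLFit and glmQLFTest) in 1 fit with a term per class and the library as a block, which left 5 residual degrees of freedom. Each class was compared with the mean of the other 5 on the log2 scale (the mean of their fitted terms), and each pair of classes with each other. A call needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. SE was computed from the log2 fold change and the F statistic. Levels are TMM-scaled CPM. For genes named as lowest in a class, a count of 0 was given the upper limit of 3 UMIs over both libraries. Other levels of 0 are printed as 0, without a limit.

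Gene lists, 25 in number, were fixed before the data were examined; 1 of them and a few single genes are not reported here, and the others are NRF2 targets; 7p11.2 neighbors of EGFR; 9p21.3; interferon-stimulated genes; MHC class I and MHC class II presentation; epithelial adhesion and keratins; mesenchymal; alveolar and lung lineage; airway secretory; S phase; G2 and M phase; hypoxia and glycolysis; cholesterol synthesis; metallothioneins; amino acid and unfolded protein response; immediate early and heat shock; NF-kB chemokines and acute phase; EGFR-MAPK feedback; cancer-testis antigens; ribosomal proteins; mitochondrial genome; blood; fibroblast and endothelium. They were tested two-sided with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over 144 pairs of list and class. Named genes followed a rule fixed before the data were examined: per class, the 8 genes with the highest and the 4 with the lowest log2 fold change among genes with adjusted p under 0.05 that were above (or below) each other class in both libraries and reached 50 CPM in at least 1 class; 2 to 4 called members with the largest change of each called list; EGFR, ALK and the markers; and the 5 genes with the largest ratio each way between the libraries. Genes of the Y chromosome, XIST and genes without a symbol were left out of the named genes. The list genes VSTM2A, SCGB1A1, SSX1, SSX2, CD3E, MS4A1, LYZ and DCN were not analysed.

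Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only, and use clusters made from all genes. Detected genes were counted after thinning each cell to 72128 UMIs, the 10th percentile of kept cells, with shallower cells left out. Between the libraries no test was made, since each is 1 library: genes of at least 50 CPM in either library in every class were listed if their log2 ratio was at least 1 in the same direction in every class. Barcode sequences were compared between the libraries, and the split of each shared cell's UMIs, gene by gene, was set against simulated readings.

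The clustering and testing steps were tested on simulated data. In 1370 simulated cells of 6 classes the clustering recovered all 6 with 8000 and with 4000 genes. The edgeR step was run on 5 simulated draws per setting of the A549-like comparison, each with 200 changed genes. With dispersions from the trend it recovered 87.5% to 91.5% of 2-fold and 96.5% to 99.5% of 4-fold changes. Its false shares were 2.16% to 5.18% and 1.99% to 4.78% of the calls by adjusted p alone. With gene-wise dispersions it recovered 79.5% to 91.0% and 95.5% to 98.5%, at false shares of 6.42% to 12.6% and 8.17% to 12.8%, above the nominal 5%. With the fold threshold as well, 0 to 3 unchanged genes were called per draw. Other comparisons were not simulated. The figures thus do not cover cluster 6, with 10 cells in Lib10, or comparisons with far more changed genes. Alternatives tried were relative log expression size factors, DESeq2 1.42.0, no filter on low counts, no library block, each library left out (1 library leaves no test, so called genes were counted whose fold in the other library alone kept its direction and the fold threshold), a UMI minimum that was 2 times as high, a mitochondrial share under 15%, no doublet removal, clusters from all genes, another random split of the genes, Leiden resolution 0.6, equal cell numbers, no fold threshold, unthinned cells, camera with an estimated correlation, and fry. Lib90 without the cell barcodes of Lib10, and clusters 4 and 6 as 1 cluster, were added after seeing the data.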

Results

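The series was built as a benchmark for single cell RNA sequencing. Its samples are pools of 5 established lung adenocarcinoma lines that were grown apart and mixed in about equal numbers. A549 carries a KEAP1 mutation, HCC827 an amplified and mutated EGFR, H2228 an EML4-ALK fusion, H1975 EGFR mutations and H838 a KEAP1 mutation. Droplet libraries with 10x version 3 chemistry gave UMI counts per gene and cell barcode, a UMI being a tag that marks 1 captured RNA molecule. Both libraries are of the same mixture, so there is 1 group with 2 libraries, Lib10 (replicate 1) and Lib90 (replicate 2). Lib10 held 31437261 UMIs over 1000 barcodes, and Lib90 held 161047294 UMIs over 3000. After the cell filters, 169 and 1332 cells remained, with 94.4% and 94.6% of the UMIs.

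The cells formed 6 classes, 3 of which carried the fixed marker genes of a line. A549-like cells had ALDH1A1 (retinaldehyde dehydrogenase, chromosome 9, 72900662 to 73080442 on GRCh38) at 3843 ± 678 CPM, against 5.79 to 11.4 in the other classes, and the fibrinogen genes FGA, FGB and FGG at 217 ± 26.7, 226 ± 54.8 and 242 ± 58.8 CPM. HCC827-like cells had EGFR, the epidermal growth factor receptor (chromosome 7, 55019021 to 55211628), at 874 ± 38.4 CPM, against 21.5 to 110.3 elsewhere, and CEACAM6 at 132 ± 4.71. H2228-like cells had ALK, the kinase whose 3' end the EML4-ALK fusion keeps (chromosome 2, 29192774 to 29921566), at 5.996 ± 0.822 CPM, against at most 0.125 elsewhere, with SAA1 at 1875 ± 208 and C3 at 238 ± 18.1 CPM. Levels here and below are TMM-scaled CPM, mean ± SD of 2 libraries, a single level after "against" is the mean of the other 5 classes, and fold changes are log2 values ± SE against the mean of the fitted log2 levels of the other 5, so a gene high in 1 other class can have a positive value and yet lie below the mean level.

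Neither the H838 nor the H1975 markers named a class, so the other classes stayed unnamed as clusters 4, 5 and 6. Most of the H838 list, made of NRF2 targets, was highest in A549-like cells, where AKR1C1, AKR1C2 and AKR1C3 reached 1196 ± 33.7, 3632 ± 480.2 and 2142 ± 228 CPM. TXNRD1 was at 670.1 ± 169 CPM in A549-like and 723 ± 139.9 in H2228-like cells, and GCLM was at 164 ± 21.7 in A549-like cells and 191 ± 21.0 in cluster 5. Of the H1975 list, NKX2-1 (a lung lineage transcription factor), NAPSA and SFTA3 were highest in HCC827-like cells, at 74.8 ± 12.5, 50.4 ± 3.997 and 6.23 ± 0.567 CPM. ROS1 lay at 0.688 to 2.70 CPM outside A549-like cells, where it had 0 UMIs. SRXN1, SFTPB and LMO3 had too few counts to be tested. Among the H2228 markers, LCN2 was also high in HCC827-like cells (7349 ± 451 CPM beside 10269 ± 949), and SLPI, a secreted protease inhibitor, was highest in cluster 5 at 1288 ± 40.0 CPM. PSPH, from the HCC827 list, was highest in cluster 4 at 84.5 ± 3.29 CPM, beside 65.6 ± 3.42 in HCC827-like cells.

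**Figure D1:**
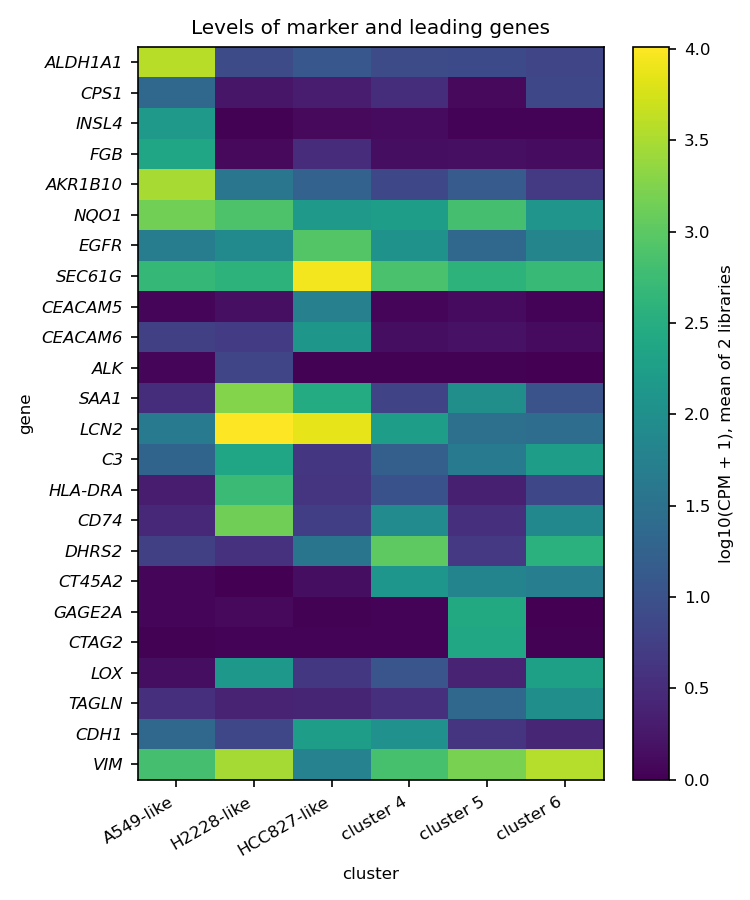
Levels of 24 marker and leading genes (vertical axis) in the 6 classes (horizontal axis), as the log10 of CPM plus 1, mean of 2 libraries, on a color scale. LCN2 is high in H2228-like (10269 CPM) and HCC827-like cells (7349 CPM), whereas GAGE2A and CTAG2 stand out in cluster 5 at 276 and 256 CPM.

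The labels say that the lines were mixed equally, so the share of each class can be set against that input, which for 5 lines is 20%. A549-like cells made up the largest class, 26.0% (95% interval 19.6 to 33.3, 44 cells) of Lib10 and 25.2% (95% interval 22.9 to 27.6, 336 cells) of Lib90, and the Lib90 interval lies above 20%. H2228-like cells held 19.5% (95% interval 13.8 to 26.3, 33 cells) and 17.4% (95% interval 15.4 to 19.6, 232 cells), and HCC827-like cells 18.9% (95% interval 13.3 to 25.7, 32 cells) and 17.0% (95% interval 14.99 to 19.1, 226 cells), with both Lib90 intervals below 20%. Cluster 4 held 18.9% (95% interval 13.3 to 25.7, 32 cells) and 19.3% (95% interval 17.2 to 21.5, 257 cells). Cluster 5 held 10.7% (95% interval 6.44 to 16.3, 18 cells) and 13.0% (95% interval 11.23 to 14.9, 173 cells), and cluster 6 5.92% (95% interval 2.87 to 10.6, 10 cells) and 8.11% (95% interval 6.70 to 9.71, 108 cells), with all 4 of these intervals below 20%. Clusters 4 and 6 may come from 1 line and were also joined, a step chosen after seeing the data. As 1 class they held 24.9% (95% interval 18.5 to 32.1, 42 cells) of Lib10 and 27.4% (95% interval 25.02 to 29.9, 365 cells) of Lib90. That Lib90 interval overlaps the interval of A549-like cells. Nearly all cells of Lib10 were also cells of Lib90, so the shares of the libraries are not independent. With a mitochondrial share under 15% in place of 25%, A549-like cells held 19.98%, H2228-like cells 21.1% and cluster 4, then the largest class, 21.5% of Lib90. Intervals are exact binomial (Clopper-Pearson) and cover counting error only. With 1 library on each side, no difference between the libraries was tested.

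**Figure D2:**
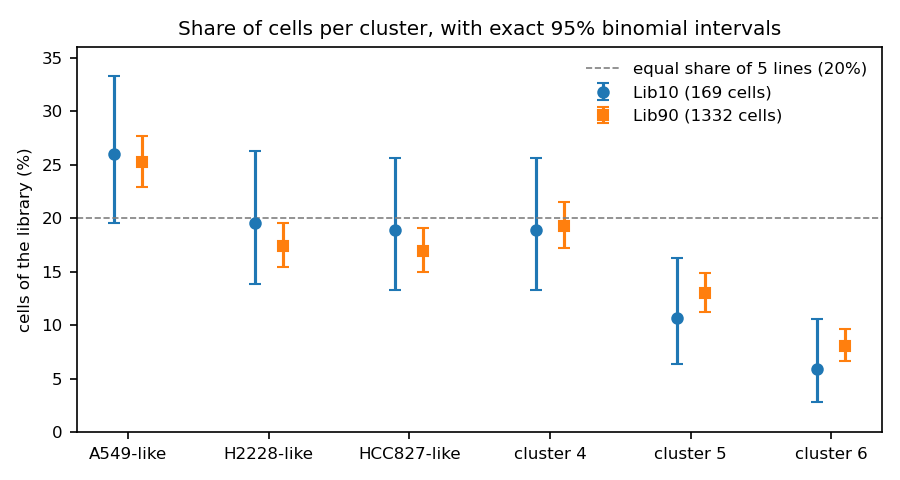
Share of each library's cells (vertical axis, percent) in each class (horizontal axis), for Lib10 (circles) and Lib90 (squares), with exact 95% binomial intervals as bars and the equal share of 20% as a dashed line. A549-like cells lie highest, at 26.0% and 25.2%, and cluster 6 lowest, at 5.92% and 8.11%.

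Cluster 4 cells held the most UMIs, with medians of 192921 in Lib10 and 123575 in Lib90. The median UMI count of H2228-like cells was 175287 in Lib10 and 116382 in Lib90, that of HCC827-like cells 181094.5 in Lib10 and 99260 in Lib90 and that of A549-like cells 148224 in Lib10 and 97906 in Lib90. Cluster 5 had 167666.5 in Lib10 and 109604 in Lib90, and cluster 6 150402 in Lib10 and 99458.5 in Lib90. With each cell thinned to 72128 UMIs, cluster 4 also had the most detected genes, medians of 8992 and 9081 in Lib10 and Lib90, followed by H2228-like cells with 8834 and 8943.5. The thinned medians were 8801.5 and 8827 in cluster 6, 8751 and 8703 in cluster 5, 8493.5 and 8433.5 in A549-like and 8472 and 8492 in HCC827-like cells. The quartiles of these classes overlap in part: in Lib90 they spanned 8842 to 9385 genes in cluster 4 and 8728 to 9136.5 in H2228-like cells. Mitochondrial transcripts took a median of 13.4% and 14.1% of the UMIs of A549-like cells, the highest of the 6 classes in each library, and 7.95% and 8.73% of those of H2228-like cells, the lowest.

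Each class was then compared with the mean of the other 5 on the log2 scale, on summed counts, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 19354 genes. A gene was called at an adjusted p under 0.05 and a fold of at least 2 (log2 of 1). Since the other classes form the reference, a list very high in 1 class can be called lower in other classes. MHC class II genes in H2228-like cells, 7p11.2 genes in HCC827-like cells and GAGE genes in cluster 5 are such cases. NRF2 targets are a related case, with 25 of 28 higher in A549-like and 17 in H2228-like cells. That list was called lower in HCC827-like cells and clusters 4 and 6. The p-values measure only how differences between classes vary between 2 libraries of 1 mixture, after the library block. That spread is estimated over all 6 classes and shares information across genes. An SE can therefore be far smaller than the gap between the values of the single libraries. The libraries also share cells: 165 of the 169 cells of Lib10 carry barcodes that are cells of Lib90 too. With those cells left out of Lib90, an alternative chosen after seeing the data, every count of calls stayed within 1.5 times its value, but among the named list members CCNE2, the S phase gene lower in A549-like cells, lost its call (adjusted p = 0.0805, log2 value -1.08 in place of -1.60). The 12 genes named first per class had adjusted p of at most 5.27e-06, and the named members of called lists at most 0.0129. With DESeq2, list members GAGE1 in H2228-like cells, HLA-DQA1 in HCC827-like cells and CCL5 in cluster 4 lost their calls (adjusted p = 0.135, 0.0838 and 0.359). Some genes near 0 in a class differed between the libraries there. Before TMM scaling, ALDH1A1 outside A549-like cells was at 1.28 to 4.61 CPM in Lib10 and 10.7 to 16.8 in Lib90. In Lib90 its UMIs were spread over 57.1% to 66.1% of the cells of each other class. Barcodes below the UMI minimum held it at 767 CPM in Lib10 and 489 in Lib90. CEACAM6 in A549-like and H2228-like cells was at 5.86 and 5.11 CPM in Lib10 and 3.22 and 3.57 in Lib90. Those levels rest on few cells, 4 of 44 and 1 of 33 in Lib10 and 19 of 336 and 29 of 232 in Lib90. The source of these low levels was not tested. Fold changes from either library alone are given where they differ by more than 1.5-fold. They are differences of log2 CPM with a prior count of 2 and not fitted values. The fitted value of both libraries can therefore lie outside the 2. Gene lists were tested with camera at a preset correlation of 0.01, which called 76 of 144 pairs of list and class. None of the 76 held in camera with a correlation estimated from the data (34 pairs had an unadjusted p under 0.05), where the smallest adjusted p was 0.0901, so that value is given beside each list. The test fry, which does not set a list against other genes, called 114. Adjusted over the list alone, the counts of higher and lower members equaled those adjusted over all genes, except for EGFR-MAPK feedback genes in A549-like cells (3 lower in place of 2) and NF-kB genes in cluster 6 (7 higher in place of 6).

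A549-like cells had high levels of detoxifying enzymes and of fibrinogens, proteins otherwise secreted by the liver, and low levels of interferon-stimulated and antigen presentation genes. ALDH1A1 was higher by a log2 value of 8.94 ± 0.12, with 10.11 from Lib10 and 8.48 from Lib90 alone, and AKR1B10, an aldo-keto reductase, by 8.04 ± 0.14, with 8.54 from Lib10 and 7.90 from Lib90 alone. Fibrinogen alpha chain FGA was higher by 8.99 ± 0.12, with 10.18 from Lib10 and 8.37 from Lib90 alone. INSL4, a placental insulin-like peptide, was at 143 ± 1.31 CPM against 0.0521 to 0.296. CPLX2, which acts in vesicle release at synapses, was at 219.8 ± 0.627 CPM against 0.395 on average elsewhere, and RBFOX3, a neuronal splicing factor (chromosome 17, 79089345 to 79516148), at 68.5 ± 1.54 against 0.107. SLC51B, GPRIN3 and TM4SF20 were likewise near 0 elsewhere and at 66.7 ± 13.7, 58.3 ± 7.38 and 206 ± 23.4 CPM here. In the other direction, the antioxidant enzyme PRDX2 was at 1.96 ± 0.222 CPM against 82.5 to 444, the interferon-induced BST2 (tetherin) at 1.47 ± 0.151 against 44.1 to 422, RAMP1 at 0.404 ± 0.357 (0.151 in Lib10 and 0.656 in Lib90) against 33.6 to 209.9, and GBP1 at 0.125 ± 0.0374 against 7.81 to 61.4. In all, 2868 genes were higher and 2737 lower, and 1734 of the higher genes exceeded each other class in both libraries. For comparison, random order of 6 classes in 2 independent libraries would put any 1 class first in both for 2.78% of all genes, a figure that does not hold for genes already called or for libraries that share cells.

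Of 28 NRF2 targets, the antioxidant genes that KEAP1 restrains, 25 were higher and 0 lower in A549-like cells (adjusted p = 5.81e-16, estimated-correlation adjusted p = 0.136), led by AKR1B10, AKR1C2 (6.39 ± 0.20) and AKR1C3 (6.12 ± 0.09). Among 52 genes of the G2 and M phases 34 were higher and 0 lower (adjusted p = 6.38e-09, estimated-correlation adjusted p = 0.476). TOP2A was at 226 ± 5.87 CPM against 57.3 and CDK1 at 71.0 ± 1.37 against 17.8; S phase genes were called up as a list with 6 higher and 1 lower of 40 (adjusted p = 0.0468, estimated-correlation adjusted p = 0.770, no longer called with relative log expression size factors, adjusted p = 0.0552). TYMS had a log2 value of 2.11 ± 0.12. In the median A549-like cell, S, G2 and M phase genes took 0.135% of the UMIs in Lib10 and 0.119% in Lib90. H2228-like cells were at 0.127% and 0.142%, so A549-like cells were highest in Lib10 alone. Interferon-stimulated genes were lower, 23 of 28 with 0 higher (adjusted p = 3.03e-12, estimated-correlation adjusted p = 0.136). IFI27 was at 9.23 ± 2.998 CPM against 1318 and IFITM3 at 11.9 ± 1.19 against 517. MHC class I presentation genes had 12 of 15 lower and 0 higher (adjusted p = 3.38e-09, estimated-correlation adjusted p = 0.126). HLA-B was at 53.8 ± 4.51 CPM against 721 and PSMB9 at 8.47 ± 0.217 against 81.4. MHC class II genes had 10 of 11 lower and 1 higher (adjusted p = 8.91e-04, estimated-correlation adjusted p = 0.263). CD74 was at 1.85 ± 1.33 (0.908 in Lib10 and 2.79 in Lib90) CPM against 312. That mean rests largely on H2228-like cells, at 1392 CPM. Clusters 4 and 6 had 85.6 and 74.0 CPM, whereas HCC827-like cells and cluster 5 were low too, at 4.54 and 2.57.

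NF-kB chemokines and acute phase genes had 16 lower and 2 higher of 24 in A549-like cells (adjusted p = 9.33e-05, estimated-correlation adjusted p = 0.275). The adhesion receptor ICAM1 was at 0.742 ± 0.621 (0.303 in Lib10 and 1.18 in Lib90) CPM against 64.9 and IL6 at 0.207 ± 0.0786 against 16.5. Metallothioneins, which bind metal ions, had 7 lower and 0 higher of 8 (adjusted p = 1.76e-04, estimated-correlation adjusted p = 0.243). MT1E was at 1.57 ± 0.935 (0.908 in Lib10 and 2.23 in Lib90) CPM against 208. Cancer-testis antigens had 9 lower and 3 higher of 19 (adjusted p = 0.0171, estimated-correlation adjusted p = 0.243). MAGEA6 was at 10.9 ± 1.71 CPM against 0.125 to 176, highest in cluster 5, and PRAME had a log2 value of 2.99 ± 0.10. Neighbors of EGFR at 7p11.2 had 2 lower and 0 higher of 13 (adjusted p = 0.00434, estimated-correlation adjusted p = 0.244), EGFR itself -1.04 ± 0.09 and LANCL2 -1.43 ± 0.13. With HCC827-like cells left aside, EGFR was at 21.5 to 110.3 CPM in the other classes, beside 48.8 here. SEC61G was at 388 to 714 in those classes, beside 467 here. Amino acid and unfolded protein response genes had 4 higher and 0 lower of 24 (adjusted p = 0.0468, estimated-correlation adjusted p = 0.538), among them the amino acid transporters SLC7A5 (1.69 ± 0.07) and SLC3A2 (1.47 ± 0.09). Genes of the mitochondrial genome had 3 higher and 0 lower of 13 (adjusted p = 3.33e-05, estimated-correlation adjusted p = 0.161). MT-ND2 was at 4925 ± 526 CPM against 2187, in the class with the highest mitochondrial share per cell.

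H2228-like cells were marked by MHC class II genes, which present antigen to T helper cells and are most abundant on immune cells, together with chemokines and acute phase proteins. HLA-DRB1 reached 724 ± 27.4 CPM against 0.938 to 5.44, HLA-DRB5 326 ± 30.6, HLA-DQA1 142 ± 28.2, HLA-DQB1 114 ± 23.7 and HLA-DPA1 273 ± 27.4. HLA genes are alike in sequence, so counts of single members are uncertain. IDO1, which breaks down tryptophan, was at 68.6 ± 15.04 CPM against 0.621, CLDN11, a tight junction protein, at 364 ± 24.96 against 1.61, and IRAK3, a brake on Toll-like receptor signaling, at 62.8 ± 9.47 against 0 to 8.30. SAA1, serum amyloid A, was higher by 6.40 ± 0.11, with 7.04 from Lib10 and 6.40 from Lib90 alone, and SAA2 by 6.29 ± 0.09. Among the lowest were PEG10 at 0.712 ± 0.122 CPM against 63.0 to 289, PRAME at 0.121 ± 0.172 (0 in Lib10 and 0.243 in Lib90) against 5.29 to 106, CT45A2 with 2 UMIs in all and ASRGL1 with 3. In all, 2971 genes were higher and 2602 lower, and 1511 of the higher genes exceeded each other class in both libraries.

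All 11 MHC class II genes were higher in H2228-like cells (adjusted p = 8.05e-09, estimated-correlation adjusted p = 0.136), as were 11 of 15 MHC class I genes with 0 lower (adjusted p = 2.07e-07, estimated-correlation adjusted p = 0.136). HLA-B was at 1977 ± 198 CPM against 337, HLA-C at 1019 ± 76.8 against 155, and the peptide trimmer ERAP2 at 57.8 ± 2.66 against 12.1. NF-kB chemokines and acute phase genes had 19 higher and 1 lower of 24 (adjusted p = 3.22e-08, estimated-correlation adjusted p = 0.182). CCL20 was at 291 ± 24.4 CPM against 9.56 and CXCL1, which attracts neutrophils, at 927 ± 54.2 against 60.6. NRF2 targets had 17 higher and 1 lower of 28 (adjusted p = 1.59e-08, estimated-correlation adjusted p = 0.203). EPHX1 was at 237 ± 16.3 CPM against 67.3, and AKR1C3 had a log2 value of 2.81 ± 0.10 although at 317 ± 22.1 CPM it lay below A549-like cells and below the mean level of the other classes (459.7). ALDH3A1 was at 205 ± 24.4 CPM, beside 495 ± 57.2 in A549-like cells and at most 2.83 elsewhere. Hypoxia and glycolysis genes had 11 higher and 0 lower of 24 (adjusted p = 2.97e-07, estimated-correlation adjusted p = 0.243), led by carbonic anhydrase CA9 (4.60 ± 0.13), ENO2 (2.25 ± 0.10) and ANGPTL4 (2.18 ± 0.15). EGFR-MAPK feedback genes had 12 higher and 0 lower of 17 (adjusted p = 5.78e-06, estimated-correlation adjusted p = 0.150). The ERK phosphatase DUSP6 was at 189.8 ± 2.18 CPM against 44.1 and PHLDA1 at 416 ± 51.4 against 108. Airway secretory genes had 10 higher and 1 lower of 16 (adjusted p = 0.00246, estimated-correlation adjusted p = 0.243). LCN2 had a log2 value of 6.21 ± 0.11 and the mucin MUC5AC 4.95 ± 0.12, with 5.57 from Lib10 and 4.60 from Lib90 alone.

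At 9p21.3, all 7 genes were lower in H2228-like cells (adjusted p = 3.69e-04, estimated-correlation adjusted p = 0.216): the cell cycle inhibitor CDKN2A was at 0.720 ± 0.797 (0.157 in Lib10 and 1.28 in Lib90) CPM against 162, MTAP had 7 UMIs (0.243 ± 0.0988 CPM against 23.3), and KLHL9 had 1. Cancer-testis antigens had 11 lower and 2 higher of 19 (adjusted p = 4.27e-04, estimated-correlation adjusted p = 0.148). PRAME had a log2 value of -6.99 ± 0.24, with -7.56 from Lib10 and -6.14 from Lib90 alone. Immediate early and heat shock genes had 4 higher and 1 lower of 19 (adjusted p = 0.0111, estimated-correlation adjusted p = 0.476). FOSL1 was at 149 ± 25.3 CPM against 25.8, IER3 at 604 ± 5.00 against 116 and the small heat shock protein HSPB1 at 59.2 ± 3.99 against 309.7. Mitochondrial genome genes had 2 lower and 0 higher of 13 (adjusted p = 3.11e-06, estimated-correlation adjusted p = 0.146), MT-ND6 and MT-ND4L, in the class with the lowest mitochondrial share per cell. Ribosomal protein genes had 3 lower and 0 higher of 36 (adjusted p = 0.00162, estimated-correlation adjusted p = 0.678).

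HCC827-like cells had the highest level of EGFR and of several of its chromosomal neighbors, and high levels of lung lineage, airway secretory and epithelial genes. SEC61G, beside EGFR at chromosome 7, 54752250 to 54759974, was at 8788 ± 233 CPM against 388 to 714, and LANCL2 and VOPP1 at 210.4 ± 0.447 and 505 ± 12.4 against 4.43 to 10.7 and 21.4 to 60.4. Farther along 7p11.2, MRPS17 was at 29.6 ± 0.894 against 3.18 to 11.1 and CHCHD2 at 2254 ± 253 against 551 to 962. SFTA2, a surfactant-associated gene, was higher by 8.39 ± 0.14, with 8.96 from Lib10 and 8.15 from Lib90 alone, and proline dehydrogenase PRODH by 7.29 ± 0.11, with 8.62 from Lib10 and 6.92 from Lib90 alone. The adhesion molecule CEACAM5 was at 55.1 ± 7.41 CPM against 0.0831 to 0.469, the calcium channel TRPC6 at 61.3 ± 6.64 against 0.0499 to 1.02, CASC9 at 65.0 ± 3.201 against 0.0347 to 10.3 and TOX3 at 82.2 ± 7.17 against 0.119 to 4.35. Beta-defensin 2 transcripts, divided between the near-identical copies DEFB4A and DEFB4B, were at 610.1 and 2537 CPM in Lib10, and at 314 and 891 in Lib90. Their highest mean in another class was 15.3 CPM, of DEFB4B in cluster 4, from 24.6 in Lib10 and 6.06 in Lib90. Among the lowest, FBXO2 was at 0.203 ± 0.287 (0 in Lib10 and 0.406 in Lib90) CPM against 6.93 to 165, CCL2 at 0.0902 ± 0.128 (0 in Lib10 and 0.180 in Lib90) against 1.67 to 72.5, CREB3L1 at 0.252 ± 0.0903 against 5.53 to 62.3 and FAM20C at 0.297 ± 0.154 (0.188 in Lib10 and 0.406 in Lib90) against 6.79 to 105. In all, 3026 genes were higher and 2291 lower, and 1661 of the higher genes exceeded each other class in both libraries.

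Epithelial adhesion and keratin genes had 22 higher and 0 lower of 26 in HCC827-like cells (adjusted p = 1.15e-11, estimated-correlation adjusted p = 0.0901). The vesicle GTPase RAB25 was at 87.3 ± 1.98 CPM against 7.02 and the epithelial splicing factor ESRP1 at 107 ± 6.43 against 17.0. Mesenchymal genes had 14 lower and 0 higher of 22 (adjusted p = 3.88e-08, estimated-correlation adjusted p = 0.136): vimentin VIM was at 59.4 ± 35.4 (84.4 in Lib10 and 34.4 in Lib90) CPM against 1941 and SPARC at 0.868 ± 0.430 (0.564 in Lib10 and 1.17 in Lib90) against 78.6. The 7p11.2 list had 10 higher and 0 lower of 13 (adjusted p = 6.02e-07, estimated-correlation adjusted p = 0.136), and all 7 genes of 9p21.3 were higher (adjusted p = 2.26e-04, estimated-correlation adjusted p = 0.203). CDKN2A was at 633 ± 31.2 CPM against 35.8. Alveolar and lung lineage genes had 10 higher and 0 lower of 15 (adjusted p = 1.89e-04, estimated-correlation adjusted p = 0.136). HOPX was at 6.40 ± 1.34 CPM against 0 to 2.16 and NAPSA had a log2 value of 5.43 ± 0.13, with 5.84 from Lib10 and 5.22 from Lib90 alone, and airway secretory genes had 12 higher and 1 lower of 16 (adjusted p = 6.54e-04, estimated-correlation adjusted p = 0.203). CEACAM6 had a log2 value of 6.81 ± 0.11 and PIGR 6.28 ± 0.19, with 7.60 from Lib10 and 5.56 from Lib90 alone. Interferon-stimulated genes had 22 higher and 1 lower of 28 (adjusted p = 6.22e-08, estimated-correlation adjusted p = 0.146). IFI44L was at 262 ± 13.9 CPM against 36.1 and IFI44 at 93.4 ± 2.64 against 18.3.

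NRF2 targets had 15 lower and 1 higher of 28 in HCC827-like cells (adjusted p = 1.41e-06, estimated-correlation adjusted p = 0.243). AKR1C1 was at 4.26 ± 4.69 (0.940 in Lib10 and 7.58 in Lib90) CPM against 293 and HMOX1 at 2.18 ± 0.685 against 21.1. Hypoxia and glycolysis genes had 9 lower and 1 higher of 24 (adjusted p = 5.72e-04, estimated-correlation adjusted p = 0.400). CA9 was at 0.0902 ± 0.128 (0 in Lib10 and 0.180 in Lib90) CPM against 19.6 and the glucose transporter SLC2A3 at 2.62 ± 1.35 (3.57 in Lib10 and 1.67 in Lib90) against 23.2. NF-kB genes moved both ways, 13 higher and 4 lower of 24 (adjusted p = 0.0177, estimated-correlation adjusted p = 0.495). CXCL5 had a log2 value of 4.27 ± 0.14, with 4.95 from Lib10 and 3.97 from Lib90 alone, IL1B of 4.22 ± 0.16 and C3 of -3.88 ± 0.16, with -4.32 from Lib10 and -3.71 from Lib90 alone. MHC class II genes had 7 lower of 11 (adjusted p = 0.0178, estimated-correlation adjusted p = 0.420), metallothioneins 3 lower of 8 (adjusted p = 0.0292, estimated-correlation adjusted p = 0.479) and cancer-testis antigens 11 lower and 2 higher of 19 (adjusted p = 0.00600, estimated-correlation adjusted p = 0.203). CD74 had a log2 value of -2.82 ± 0.15, MT1E -1.92 ± 0.21, with -1.04 from Lib10 and -2.23 from Lib90 alone, and CT83 was at 42.8 ± 0.110 CPM against 0.0164 to 28.8. Ribosomal protein genes had 7 higher and 0 lower of 36 (adjusted p = 2.82e-09, estimated-correlation adjusted p = 0.476). RPL7 was at 1399 ± 28.7 CPM against 205 and RPL23 at 2841 ± 457 against 1035; counts of ribosomal protein genes are uncertain, since their pseudogenes share their sequence. G2 and M phase genes had 9 higher and 0 lower of 52 (adjusted p = 0.00324, estimated-correlation adjusted p = 0.684), CDC20 with a log2 value of 1.47 ± 0.15, with 2.40 from Lib10 and 1.00 from Lib90 alone, and S phase genes 3 higher and 0 lower of 40 (adjusted p = 0.0428, estimated-correlation adjusted p = 0.770, no longer called with relative log expression size factors, adjusted p = 0.0505). RRM2 had a log2 value of 1.49 ± 0.18, with 2.19 from Lib10 and 1.19 from Lib90 alone. These calls are of summed counts. In the median HCC827-like cell, S, G2 and M phase genes took 0.115% of the UMIs in Lib10 and 0.0945% in Lib90. The latter was the lowest of the classes in Lib90, where H2228-like cells were highest at 0.142%. The mitochondrial genome list was called up (adjusted p = 9.36e-04, estimated-correlation adjusted p = 0.232) with no member past the fold threshold.

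Cluster 4 had high levels of interferon-stimulated and epithelial genes. IFI27 was at 3899.6 ± 448 CPM against 539.6, and DHRS2, a short-chain dehydrogenase (chromosome 14, 23630115 to 23645639), at 1031 ± 219 against 2.78 to 367. MIR205HG, the host of the epithelial microRNA miR-205, was at 197 ± 4.19 CPM against 0.529 to 55.2 and the ion transport regulator FXYD3 at 78.3 ± 11.8 against 0.381 to 32.2. The near-identical CT45A2, CT45A8 and CT45A9 were at 126 ± 2.34, 52.4 ± 0.662 and 80.8 ± 1.02 CPM, with the next class at 63.1, 19.4 and 24.6. CT45A1 was at 20.7 CPM here and 39.3 in cluster 5, and cancer-testis antigens were not called as a list in cluster 4, with 10 lower and 4 higher of 19 (adjusted p = 0.100, estimated-correlation adjusted p = 0.393). The noncoding LINC01511 was higher by 6.25 ± 0.16, with 6.74 from Lib10 and 5.63 from Lib90 alone, and LINC01610 by 5.93 ± 0.17, with 6.82 from Lib10 and 5.22 from Lib90 alone. Lowest were WFDC21P at 0.649 ± 0.497 (0.298 in Lib10 and 1.00 in Lib90) CPM against 2.30 to 143, the protease inhibitor SERPINE2 at 0.501 ± 0.498 (0.149 in Lib10 and 0.854 in Lib90) against 0.817 to 181, PRRX2 at 0.295 ± 0.207 (0.149 in Lib10 and 0.442 in Lib90) against 1.41 to 88.7 and SAA2 at 0.547 ± 0.142 against 0.571 to 284. In all, 3164 genes were higher and 1773 lower, and 1456 of the higher genes exceeded each other class in both libraries.

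All 28 interferon-stimulated genes were higher in cluster 4 (adjusted p = 6.17e-15, estimated-correlation adjusted p = 0.126). IFIT1, which binds viral RNA, was at 139 ± 17.5 CPM against 14.9, XAF1 at 186 ± 14.5 against 37.4 and the transcription factor IRF7 at 113 ± 2.33 against 14.9. Epithelial adhesion and keratin genes had 21 higher and 0 lower of 26 (adjusted p = 1.10e-10, estimated-correlation adjusted p = 0.0901). MAL2 had a log2 value of 5.03 ± 0.10 and ESRP1 4.90 ± 0.12, with 5.74 from Lib10 and 4.59 from Lib90 alone. All 7 genes of 9p21.3 were higher (adjusted p = 0.00143, estimated-correlation adjusted p = 0.243). CDKN2A, at 131 ± 0.634 CPM, was below HCC827-like cells and above the 4 other classes. Metallothioneins had 6 higher and 0 lower of 8 (adjusted p = 0.00900, estimated-correlation adjusted p = 0.411). MT1E was at 628 ± 71.5 CPM against 82.7 and MT2A at 2062 ± 191 against 594. NRF2 targets had 17 lower and 1 higher of 28 (adjusted p = 1.41e-09, estimated-correlation adjusted p = 0.182), including the drug exporter ABCC2 (-4.77 ± 0.37, with -5.41 from Lib10 and -4.37 from Lib90 alone) and PGD of the pentose phosphate pathway (-2.87 ± 0.10). S phase genes had 17 lower and 0 higher of 40 (adjusted p = 7.82e-06, estimated-correlation adjusted p = 0.538) and G2 and M phase genes 18 lower and 0 higher of 52 (adjusted p = 5.91e-06, estimated-correlation adjusted p = 0.563). TYMS was at 4.09 ± 1.58 CPM against 36.1 and TOP2A at 16.8 ± 12.8 (7.74 in Lib10 and 25.9 in Lib90) against 99.1. In the median cluster 4 cell, S, G2 and M phase genes took 0.0860% of the UMIs in Lib10, the lowest of the classes. Their share was 0.0977% in Lib90, above HCC827-like cells at 0.0945%. NF-kB genes had 12 lower and 2 higher of 24 (adjusted p = 0.0171, estimated-correlation adjusted p = 0.495). SAA1 had a log2 value of -3.80 ± 0.21, with -2.58 from Lib10 and -3.97 from Lib90 alone, and BIRC3 -3.10 ± 0.16. Ribosomal protein genes had 3 lower and 0 higher of 36 (adjusted p = 5.03e-04, estimated-correlation adjusted p = 0.653). RPS16 had a log2 value of -1.94 ± 0.08.

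Cluster 5 was set apart by cancer-testis antigens, proteins normally limited to germ cells, and by very low epithelial genes. GAGE family counts led: GAGE12D was at 1010.4 ± 128 CPM, GAGE12G at 518 ± 68.7, GAGE12J at 468 ± 93.9, GAGE2E at 397 ± 53.8, GAGE2A at 276 ± 32.3, GAGE12H at 264 ± 45.8 and GAGE12C at 163 ± 53.5, and the highest of the 7 in another class was 0.488 CPM. These copies are near-identical, so how the counts divide among them is uncertain. CTAG2, of the NY-ESO-1 family (chromosome X, 154651972 to 154653579), was at 256 ± 20.1 CPM against 0.0416 to 0.0902. The keratin KRT19 was at 5.97 ± 3.21 (3.71 in Lib10 and 8.24 in Lib90) CPM against 801. Among the lowest were XAGE1A at 1.55 ± 1.76 (0.309 in Lib10 and 2.80 in Lib90) CPM against 56.5 to 651, the synaptic vesicle protein SYT1 at 0.279 ± 0.0418 against 8.66 to 79.7, and KCNQ1OT1 and THSD7A, with 3 and 1 UMIs in all. In all, 3601 genes were higher and 2978 lower, more than in any other class, and 2499 of the higher genes exceeded each other class in both libraries.

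Cancer-testis antigens had 17 higher and 2 lower of 19 in cluster 5 (adjusted p = 2.29e-07, estimated-correlation adjusted p = 0.126). GAGE1 and MAGEC1 were at 133 ± 24.6 and 15.1 ± 3.59 CPM. Epithelial adhesion and keratin genes had 23 lower and 0 higher of 26 (adjusted p = 4.06e-10, estimated-correlation adjusted p = 0.0901). SPINT2 was at 6.30 ± 3.66 (3.71 in Lib10 and 8.89 in Lib90) CPM against 272 and the epithelial transcription factor ELF3 at 2.02 ± 1.10 (1.24 in Lib10 and 2.80 in Lib90) against 105. Interferon-stimulated genes had 24 lower and 1 higher of 28 (adjusted p = 2.68e-09, estimated-correlation adjusted p = 0.136), MHC class I genes 9 lower and 1 higher of 15 (adjusted p = 7.24e-04, estimated-correlation adjusted p = 0.183), and MHC class II genes 10 lower and 0 higher of 11 (adjusted p = 2.28e-04, estimated-correlation adjusted p = 0.243). IRF7 was at 0.2497 ± 0.353 (0 in Lib10 and 0.499 in Lib90) CPM against 37.4, HLA-B at 34.2 ± 2.71 against 725 and CD74 at 2.57 ± 1.45 (1.54 in Lib10 and 3.60 in Lib90) against 312. Alveolar and lung lineage genes had 12 lower and 0 higher of 15 (adjusted p = 2.26e-04, estimated-correlation adjusted p = 0.136). FOXA2 was at 0.150 ± 0.212 (0 in Lib10 and 0.2996 in Lib90) CPM against 19.9 and NKX2-1 at 0.2996 ± 0.424 (0 in Lib10 and 0.599 in Lib90) against 24.2. Airway secretory genes had 10 lower and 2 higher of 16 (adjusted p = 0.0319, estimated-correlation adjusted p = 0.381). AGR2 was at 4.11 ± 2.31 (2.47 in Lib10 and 5.74 in Lib90) against 384.

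The 7p11.2 list had 6 lower and 0 higher of 13 in cluster 5 (adjusted p = 1.09e-04, estimated-correlation adjusted p = 0.173). EGFR had a log2 value of -2.49 ± 0.11 and PSPH -2.06 ± 0.11. At 9p21.3, 6 of 7 genes were lower and 0 higher (adjusted p = 0.00162, estimated-correlation adjusted p = 0.243). MTAP was at 0.325 ± 0.459 (0 in Lib10 and 0.649 in Lib90) CPM against 23.3. EGFR-MAPK feedback genes had 8 lower and 0 higher of 17 (adjusted p = 0.00368, estimated-correlation adjusted p = 0.263). DUSP6 was at 2.85 ± 0.978 CPM against 81.5 and the EGFR ligand EREG at 1.25 ± 1.77 (0 in Lib10 and 2.50 in Lib90) against 70.0. S phase genes had 8 lower and 1 higher of 40 (adjusted p = 0.00278, estimated-correlation adjusted p = 0.661) and G2 and M phase genes 7 lower and 2 higher of 52 (adjusted p = 0.00987, estimated-correlation adjusted p = 0.733). UHRF1 had a log2 value of -1.61 ± 0.26, with -2.92 from Lib10 and -1.41 from Lib90 alone, and HMGB2 -1.99 ± 0.13, with -2.56 from Lib10 and -1.86 from Lib90 alone. In the median cluster 5 cell, genes of both phase lists took 0.0933% of the UMIs in Lib10 and 0.107% in Lib90, above clusters 4 and 6 in both. NRF2 targets were not called as a list, with 10 higher and 5 lower of 28 (adjusted p = 0.314, estimated-correlation adjusted p = 0.776). NQO1 at 667 ± 59.2 CPM and GCLM at 191 ± 21.0 were above clusters 4 (174 ± 25.2 and 24.1 ± 2.49) and 6 (123 ± 9.50 and 25.9 ± 0.962).

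Cluster 6, the smallest class, was high in mesenchymal genes and low in epithelial, secretory and NRF2 genes. TAGLN, a smooth muscle actin-binding protein, was at 98.8 ± 47.4 (65.2 in Lib10 and 132 in Lib90) CPM against 1.49 to 21.2, LOX, which cross-links collagen, at 193 ± 58.1 against 0.414 to 139, and matrix Gla protein MGP at 51.1 ± 7.39 against 0.0347 to 3.76. The trypsinogen PRSS2 was at 93.7 ± 49.7 (129 in Lib10 and 58.6 in Lib90) CPM against 0 to 2.26, with UMIs in 4 of 10 and 38 of 108 cells, beside 5 of 32 and 21 of 257 cells of cluster 4 and 2 of 32 and 5 of 226 HCC827-like cells. The interleukin-7 receptor IL7R was at 56.9 ± 20.2 CPM against 0.158 to 14.0, the chemokine CCL2 at 72.5 ± 18.1 against 0.0902 to 33.0, PLK5 at 54.0 ± 3.66 against 0.0250 to 21.9 and NFE4 at 61.1 ± 19.1 against 0.125 to 45.9. DAB2, IRAK3 and mesothelin MSLN had 0 UMIs in either library, which allows up to 0.229 CPM over both, against 0.252 to 54.2, 0.237 to 62.8 and 0.311 to 80.7 in the other classes. S100P was at 0.885 ± 0.312 CPM against 8.06 to 203. In all, 2105 genes were higher and 1942 lower, and 755 of the higher genes exceeded each other class in both libraries, the fewest of the 6 classes. Sums of cluster 6 rest on 10 cells in Lib10 and 108 in Lib90.

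Mesenchymal genes had 14 higher and 2 lower of 22 in cluster 6 (adjusted p = 3.74e-05, estimated-correlation adjusted p = 0.150). COL5A1 was at 89.4 ± 44.3 (58.1 in Lib10 and 121 in Lib90) CPM against 9.24. Markers of fibroblasts and endothelium had 4 higher and 0 lower of 6 tested (adjusted p = 0.0476, estimated-correlation adjusted p = 0.345, no longer called with relative log expression size factors, adjusted p = 0.0552). COL1A2 was at 2.76 CPM in Lib10 and 52.3 in Lib90, COL1A1, which is also in the mesenchymal list, at 26.5 and 123, and PDGFRB at 1.55 ± 0.628. Epithelial adhesion and keratin genes had 17 lower and 1 higher of 26 (adjusted p = 1.31e-04, estimated-correlation adjusted p = 0.136). ESRP1 was at 0.249 ± 0.353 (0 in Lib10 and 0.499 in Lib90) CPM against 38.4 and MAL2 at 1.62 ± 0.0565 against 99.7. NRF2 targets had 21 lower and 1 higher of 28 (adjusted p = 2.59e-12, estimated-correlation adjusted p = 0.150). AKR1C2 had a log2 value of -4.78 ± 0.46, with -5.26 from Lib10 and -4.59 from Lib90 alone, and ABCC2 -4.81 ± 0.33, with -3.88 from Lib10 and -4.62 from Lib90 alone. EGFR-MAPK feedback genes had 14 lower and 0 higher of 17 (adjusted p = 8.20e-06, estimated-correlation adjusted p = 0.150), including the EGFR ligands AREG (-3.22 ± 0.21) and EREG (-2.21 ± 0.18), and airway secretory genes 12 lower and 1 higher of 16 (adjusted p = 3.33e-05, estimated-correlation adjusted p = 0.150). AGR2 had a log2 value of -5.16 ± 0.18, with -5.77 from Lib10 and -5.05 from Lib90 alone.

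Interferon-stimulated genes had 14 higher and 0 lower of 28 in cluster 6 (adjusted p = 7.82e-06, estimated-correlation adjusted p = 0.182). BST2 was at 422 ± 44.9 CPM against 156 and XAF1 at 107 ± 7.84 against 53.3. MHC class I genes had 6 higher and 0 lower of 15 (adjusted p = 3.16e-07, estimated-correlation adjusted p = 0.136). ERAP2 had a log2 value of 2.41 ± 0.13 and PSMB9 1.65 ± 0.09. S phase genes had 6 higher and 0 lower of 40 (adjusted p = 9.33e-05, estimated-correlation adjusted p = 0.583). CDC45 had a log2 value of 1.80 ± 0.21, with 2.67 from Lib10 and 1.61 from Lib90 alone, and UHRF1 1.61 ± 0.20, with 2.94 from Lib10 and 1.23 from Lib90 alone. Hypoxia and glycolysis genes had 5 higher and 0 lower of 24 (adjusted p = 0.00988, estimated-correlation adjusted p = 0.516), CA9 with a log2 value of 3.73 ± 0.16 and EGLN3 2.16 ± 0.11, with 1.59 from Lib10 and 2.31 from Lib90 alone. The mitochondrial genome list was called down (adjusted p = 0.00278, estimated-correlation adjusted p = 0.243) with no member past the fold threshold. Cholesterol synthesis genes were called as a list in no class, the lowest adjusted p being 0.0911 in HCC827-like cells with 7 higher and 2 lower of 22, and of the blood cell markers 1 of 14 had enough counts to be tested, so that list had no test.

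Pairs of classes were compared in the same fit. Clusters 4 and 6 differed least, with 2488 genes higher in cluster 4 and 1414 higher in cluster 6. HCC827-like cells and cluster 5 differed most, with 4150 and 4168 genes, but without the shared cells in Lib90 clusters 4 and 5 did, with 4119 and 3931 genes beside 3977 and 4046. Between clusters 6 and 4, epithelial adhesion and keratin genes had 23 lower in cluster 6 and 0 higher of 26 (adjusted p = 3.30e-13, estimated-correlation adjusted p = 0.0241), which passed the threshold with the estimated correlation too; ESRP1 was at 0.249 ± 0.353 (0 in Lib10 and 0.499 in Lib90) CPM in cluster 6 and 77.8 ± 2.84 in cluster 4. Mesenchymal genes had 12 higher and 0 lower of 22 (adjusted p = 1.97e-05, estimated-correlation adjusted p = 0.148), interferon-stimulated genes 21 lower and 0 higher of 28 (adjusted p = 8.07e-08, estimated-correlation adjusted p = 0.148), and S phase genes 22 higher and 0 lower of 40 (adjusted p = 7.15e-11, estimated-correlation adjusted p = 0.402). The calls are of summed counts. In the median cell, S, G2 and M phase genes together took similar shares of the UMIs in clusters 6 and 4. These were 0.0912% and 0.0860% in Lib10, and 0.0990% and 0.0977% in Lib90. Cluster 5 set against the mean of clusters 4 and 6 had 17 NRF2 targets higher and 2 lower of 28 (adjusted p = 2.29e-05, estimated-correlation adjusted p = 0.315) and 23 epithelial genes lower and 1 higher of 26 (adjusted p = 2.43e-09, estimated-correlation adjusted p = 0.0572). These list contrasts of unnamed clusters were chosen after the classes were seen.

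Most genes were at a similar level in both libraries, and the largest differences were in pseudogenes of abundant proteins. Of 1572 genes with at least 50 CPM in either library in every class, 85.7% had a mean log2 ratio of Lib90 over Lib10 within 0.25 of 0. Of these genes, 12 were at least 2-fold higher in Lib10 in all 6 classes at once, and 0 were at least 2-fold higher in Lib90 in all 6. Genes that differed in only some classes were not counted. The largest ratios were of RPL8P4, a pseudogene of ribosomal protein L8 (mean log2 ratio -4.43), RPS29P11 (-4.38), TPT1P4 (-3.67) and RPL5P12 (-2.11), whose counts are uncertain because reads can also match the parent gene. The cytokine MIF was also lower in Lib90, at 119.6 CPM against 398 in Lib10 (log2 ratio -1.74). Toward Lib90, the largest ratios were 0.70 for FTH1P20, 0.64 for RPL5P17, 0.41 for ID1 and 0.35 for UBE2S. With 1 library on each side these are sizes with no test.

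Cell barcodes of the smaller library recurred in the larger. Of the 182 barcodes of Lib10 above its UMI minimum, 176 were above the minimum of Lib90 too (96.7%, exact 95% interval 93.0 to 98.8). Their UMI totals in Lib90 were 0.636 ± 0.0828 (SD over barcodes) of those in Lib10. All 165 cells kept in both had the same class in both, among them 44 A549-like and 10 cluster 6 cells. The other 1167 cells of Lib90 were not cells of Lib10, and each library was counted as 1 replicate.

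**Figure D3:**
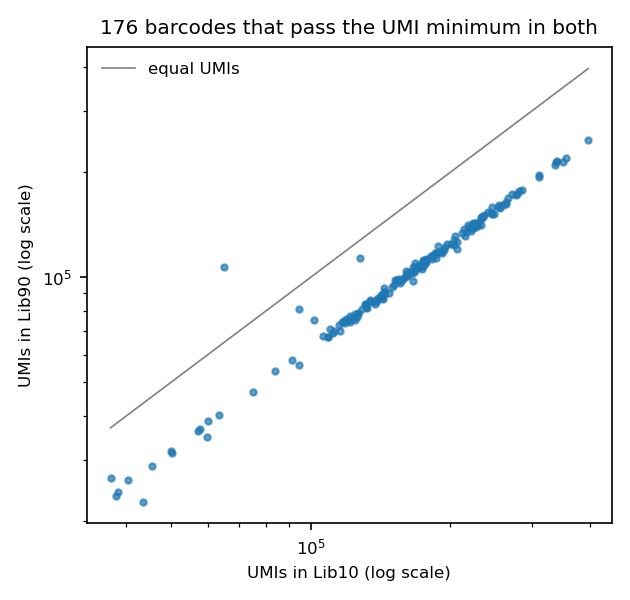
UMIs of the 176 barcodes above the UMI minimum in both libraries, in Lib10 (horizontal axis, log scale) and Lib90 (vertical axis, log scale), 1 point per barcode, with a line of equal UMIs. 175 of the points lie below the line, and the ratio of Lib90 to Lib10 had a mean of 0.636, from 0.522 to 1.64.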

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

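The tests of the shared barcodes were chosen after the recurrence had been seen. Cell barcode sequences, which no comparison uses, showed 176 barcodes above the UMI minimum of both libraries, a signal in data outside the comparisons. Of the cells kept in both libraries, 100% had the same class in both, against 19.3% for unrelated cells, which argues against barcode sequences drawn by chance for unrelated cells. The median UMI count of shared barcodes was 0.994 times that of the other cells of Lib90, which argues against a few reads of Lib10 assigned to Lib90 through its index. A larger share of reads assigned in that way would hold the same molecules, so this test cannot exclude it. The split of UMIs between the libraries had a median dispersion of 0.415 per cell (quartiles 0.400 to 0.439), between the 0.999 of simulated independent readings and the 0.223 of simulated readings of the same molecules, so a candidate explanation is that part of the UMIs of these cells come from the same cDNA molecules in both libraries. No biological explanation was tested, since the design has 1 group.

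Barcodes below the UMI minimum, which no comparison uses, held 827548 UMIs in Lib10 (2.63% of its UMIs, 814 barcodes) and 3217693 in Lib90 (2.00%, 1589 barcodes). Across genes, which are not independent replicates, their summed profile correlated with that of the kept cells at r = 0.963 in Lib10 and 0.978 in Lib90. The 12 barcodes of Lib10 and 57 of Lib90 removed for a mitochondrial share of 25% or more had median shares of 55.3% and 56.3%.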

How the results depend on the processing

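The alternatives without the shared barcodes and with clusters 4 and 6 joined were chosen after the data had been seen; the others were planned. Of 363 alternative counts, shares and medians, 311 stayed within 1.5 times the count or within the interval or spread, and 52 moved. For 24 of them, at Leiden resolution 0.6, clusters were matched back to the 6 classes by shared cells (8 clusters from each random set of genes). A finer split of a class could not move these 24 values, and all stayed the same. With no fold threshold, genes higher and lower numbered 6709 and 5963 in A549-like cells, 6827 and 5771 in H2228-like cells, 6586 and 5825 in HCC827-like cells, 6808 and 5450 in cluster 4, 6894 and 6150 in cluster 5 and 5040 and 4722 in cluster 6, since smaller changes then count. With 10 cells drawn per class and library they numbered 1549 and 1151 in A549-like cells, 1695 and 1217 in H2228-like cells, 1725 and 1004 in HCC827-like cells, 1691 and 771 in cluster 4, 1995 and 1501 in cluster 5 and 1136 and 771 in cluster 6, from fewer cells. With no filter on low counts, 38957 genes were tested in place of 19354, and the genes called higher rose in number in every class. The 1 count that moved was of genes higher in cluster 4, 4888 in place of 3164. In cluster 5, for comparison, they numbered 5300 in place of 3601. The cause was not tested. Lists called numbered 0 in each class with camera's estimated correlation, and fry, which tests a list by itself, called 19 in H2228-like cells and 19 in cluster 4. With a mitochondrial share under 15%, the Lib90 shares were 19.98% A549-like, 21.1% H2228-like, 21.5% cluster 4, 10.4% cluster 5 and 9.72% cluster 6, so that A549-like cells, highest in mitochondrial share, were no longer above 20%. Of 4047 genes called in cluster 6, 3406 were called with that filter too. The direction was opposite for 18 of them, beside 1 in cluster 4 and 0 in each other class. Unthinned cells had median genes in Lib10 and Lib90 of 10653 and 9351 (A549-like), 11554 and 10412.5 (H2228-like), 11451 and 9452 (HCC827-like), 11996 and 10808 (cluster 4), 11482 and 10015 (cluster 5) and 11107.5 and 9835 (cluster 6), since deeper cells show more genes. At the higher UMI minimum, cluster 6 cells of Lib90 had a median of 104674.5 UMIs, and the class held 120 cells in place of 108. Cluster 4 held 235 in place of 257. That filter only removes cells, so some cells changed to cluster 6, whose border depends on the filter. The cause was not tested. With clusters 4 and 6 joined, they held 27.4% of Lib90.

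For named genes a call here means an adjusted p under 0.05, with no fold threshold. Of 2136 alternative fold changes of named genes, 2078 kept their direction and, where a test was made, their side of that threshold (527 without replicate 1 and 523 without replicate 2 were compared by direction alone, since 1 library leaves no test). In the same direction, 32 lost the call (26 with DESeq2 and 6 without the shared barcodes) and 3 gained one. Turns in direction numbered 19 among values not called with both libraries and 4 among called ones. The last were CCL5 in cluster 4, 2.89 with both libraries, 2.55 without replicate 1 and -1.82 without replicate 2; IFIT2 in cluster 6, 2.28 with both libraries, 2.61 without replicate 1 and -0.58 without replicate 2; TFF1 in cluster 6, 4.01 with both libraries, 3.34 without replicate 1 and -2.20 without replicate 2; and LANCL2 in cluster 4, -0.39 with both libraries, -0.50 without replicate 1 and 0.00974 without replicate 2; the cause was not tested. Sums of cluster 6 in Lib10 rest on 10 cells, which limits their precision.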

Other observations

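The tests of stretches of genes, of droplets with 2 cells and of clusters 4 and 6 as 1 line were chosen after the results had been seen; the cell cycle test was set before its result was seen. Neighboring genes differed together in each class. In stretches of 20 protein-coding genes, HCC827-like cells were lowest on chromosome 10 (7818504 to 17715914), around VIM, with a median log2 value of -1.78 against the other classes. A549-like cells were highest on chromosome 19 (38878555 to 40426025), around AKT2, at 1.56, where clusters 4 and 6 were low (-1.33 and -1.25 in overlapping stretches). H2228-like cells were lowest on chromosome 17 (7626234 to 15265357), at -1.50. After a stretch of GAGE genes on chromosome X, cluster 5 was highest on chromosome 12 (21501781 to 27803040), at 2.00. Each of these lay beyond the most extreme stretch of 1000 shuffled gene orders of its class. That extreme was -1.09 in HCC827-like cells, 0.90 in A549-like cells, -0.82 in cluster 4 and -0.84 in cluster 6. It was -0.99 in H2228-like cells and 1.07 in cluster 5. These stretches were picked as the most extreme, and multi-copy families such as GAGE, CT45, HLA and zinc finger genes add to some of them.

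The highest stretch of HCC827-like cells lay on chromosome 8 (70109762 to 81759515), with RPL7 and TPD52, at a median of 1.46, and 16 of its 20 genes were higher. Of 1000 shuffled gene orders, 0 had a stretch as high, and the highest reached 0.847, which argues against chance order. The stretch around EGFR was next, at 1.20. A difference in DNA copies in these lines is a candidate explanation, but DNA was not measured, and shared regulation of neighbors stays open too.

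Cluster 6 stood apart from cluster 4, its nearest class. Droplets with a cell of cluster 4 and a cell of another class would lie between the 2, but 113 genes were at least 2 times above each other class in both libraries, which argues against them. Another phase of the cell cycle would shrink the difference among cells of low cell cycle expression, but the median log2 ratio of the epithelial list between clusters 6 and 4 was -2.98 in all cells and -3.62 in those cells, 122% of it, which argues against the cycle. Most of the rise came from Lib10, from -2.81 to -3.92 with 7 cluster 6 cells left. In Lib90, with 47 left, the ratio went from -3.15 to -3.32. A hypothesis is that clusters 4 and 6 are 2 states of 1 line: over 393 stretches of neighboring genes their deviations correlated at r = 0.438 (rho = 0.344; stretches are not independent replicates), and the next highest of the 15 pairs of classes, HCC827-like cells and cluster 4, at 0.00700, or 0.698 and 0.365 with deviations from the other 4 classes. Compared classes share controls in both forms, so only the order of the pairs is read, which may also hold for lines with similar chromosomes. Still, 6 classes cannot all be different lines in a mixture of 5. If the named classes are A549, HCC827 and H2228, clusters 4, 5 and 6 come from H838 and H1975. At least 2 of them then share a line. With cluster 5, clusters 4 and 6 ranked low, at -0.414 and -0.290, which argues against cluster 5 as 1 of that pair. No cell was genotyped, so the line of each cluster stays open.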
